A study of Homo sapiens with 2 samples.

How the data were processed

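Total RNA of MDA-MB-231 cells was enriched for polyadenylated RNA with oligo(dT) beads, fragmented, reverse transcribed and made into Illumina libraries, per the labels' protocols, with 1 library from cells given a negative-control siRNA and 1 from cells given an siRNA against HNRNPF. The kit named in the labels' protocols does not by itself settle whether strand was kept, and whether counting used strand is not given in the sources used here. The submitters' processing notes name fastp 0.18.0, HISAT2, StringTie 1.3.1 and RSEM and the genome build GRCh38, without their roles or order, and the annotation release is not given in the sources used here.

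The deposited table held 20323 genes with Ensembl identifiers. Its estimated counts (expected counts as RSEM gives them, tested on the file: not whole in 11.6% and 12.0% of genes) were deposited by the authors without scaling between libraries, in 1 column per library per the file headers. The table also held the authors' FPKM per library, the authors' log2 fold change, which equals the log2 ratio of the FPKM columns with 0 set to 0.001 within 3.1e-09 for every gene, and the authors' p-value and false discovery rate, whose test is not given in the sources used here. Another 2 columns of per-library values, carrying means, and 3 values in a column without a name were not used. The library names in the table were matched to the labels by the negative control's name and by the table's own name, which sets that control against the HNRNPF siRNA; the second library's column is named si848. Symbols came from the table, with 74 blanks filled from the Ensembl name table, in which 20301 of the 20323 identifiers were found; where rows shared a symbol (965 rows), the row that owns it in the name table kept it and the others were called by identifier. Coordinates, transcript lengths, GC content and 3' UTRs came from GENCODE release 29 on GRCh38, which held 20171 of the identifiers, 19769 of them protein-coding.

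Estimated counts were rounded to whole numbers. Effective library sizes were 20471293 for the control and 20314875 for the HNRNPF siRNA library by the trimmed mean of M values (TMM, edgeR 4.0.16 in R 4.3.3), and the log2 ratio of CPM (counts scaled to a library of 1e6) was taken with a prior count of 2, HNRNPF siRNA over control. A gene was expressed if it reached 1 CPM and 20 counts in the higher library. Intervals of a ratio are exact 95% Clopper-Pearson intervals of the share of both libraries' counts (scipy 1.17.1), scaled by the effective library sizes. They cover counting error only, since reads amplified without molecular identifiers are not independent molecules and no replicate shows the spread between cultures. With 1 library per group no test was run and genes were counted by size, at 2-fold. The test for several libraries per group that had been planned was not run.

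For 46 gene lists the median log2 ratio of the expressed members was taken, and for the 40 lists with at least 5 expressed members its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. The rules, lists and main alternatives were fixed before the data were examined. The genes named were HNRNPF with HNRNPH1, HNRNPH2, HNRNPH3 and GRSF1; the 12 genes with the largest and the 12 with the smallest log2 ratio among genes with a symbol at 5 CPM and 50 counts or more in the higher library, leaving out clone names; the 3 members of each list, at that level, with the largest absolute log2 ratio; and the members of any list of 6 genes or fewer. Any other gene named was chosen after its value was seen, and some genes that this rule selects are not reported here.

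The 3' UTR of each gene was that of its principal protein-coding transcript with the longest 3' UTR. All 16044 heptamers found in at least 60 of 10561 genes were scored by the mean log2 ratio of their carriers, limited to plus or minus 2 and with the trend of 3' UTR length and GC content removed, divided by the standard error of that mean among these genes. To guard against picking and testing on the same genes, the heptamer was also picked on alternate genes and counted in those left. The trend of the log2 ratio with transcript GC content and length, available for 99.7% of expressed genes, was a quadratic surface fitted over expressed genes.

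The ratio was tested on simulated data with 20323 genes at the real levels and depths. With counting error alone 98% of genes changed 3-fold passed 2-fold, and with an added biological dispersion of 0.04 this was 92%. The list percentile was tested on 600 random lists of 22 genes, of which 6.70% lay outside the central 95%, and on 50 lists moved by 0.3, all of which lay above it. The heptamer score found a shift put on a single heptamer. For counting error, the summed counts of each gene were divided between the libraries at random 200 times by the effective library sizes, with the same expression minimum. Alternatives were size factors by relative log expression (DESeq2 1.42.0), the upper quartile, total counts, the authors' FPKM with 0.1 added, prior counts of 0.5 and 5, other minimum levels and folds, the mean in place of the median, library sizes without mitochondrially encoded and ribosomal protein genes, the authors' own fold changes, and, added later, the removal of the GC and length trend, of genes with the heptamer, of genes that share reads and of genes that GENCODE does not annotate as protein-coding. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the rest.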

Results

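Polyadenylated RNA was sequenced from MDA-MB-231 cells, a line derived from a triple-negative breast cancer, after transfection of a small interfering RNA (siRNA) against HNRNPF or of a negative-control siRNA. HNRNPF encodes heterogeneous nuclear ribonucleoprotein F, an RNA-binding protein that recognises G-rich sequences and takes part in splicing and polyadenylation. The comparison asked which transcripts changed in level when HNRNPF was depleted. Each group held 1 library, so no difference below has a replicate check and no p-value was computed; higher and lower refer to these 2 libraries, and the 95% intervals cover counting error only. The control library held 20654622 estimated counts over 14656 genes with a count above 0, and the HNRNPF siRNA library 20134572 counts over 14768 genes. In the table the second library carries the name of an siRNA, si848, and was taken as the HNRNPF siRNA library because the authors named the table as negative control against HNRNPF siRNA and the other library carries the control's name.

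HNRNPF transcripts were at 38.8% of their control level. The gene (ENSG00000169813, GRCh38 chromosome 10, 43385617 to 43409166, minus strand) had 6373 counts, 311 CPM (counts scaled to a library of 1e6), in the control library and 2451 counts, 121 CPM, in the HNRNPF siRNA library. The log2 ratio was -1.37 (exact 95% interval -1.44 to -1.30), 2.58-fold lower. The closest paralogs, which bind similar G-rich motifs, stayed near their control level. HNRNPH1 had a log2 ratio of 0.01 (95% interval -0.02 to 0.04) and HNRNPH3 a log2 ratio of 0.03 (95% interval -0.04 to 0.09). HNRNPH2 was lower by a small margin, with a log2 ratio of -0.21 (95% interval -0.29 to -0.13), and so was GRSF1, at -0.11 (95% interval -0.18 to -0.03). Some HNRNPH2 reads were shared between genes by the authors' counting, so its value is less certain. Among the 26 other hnRNP genes 18 were lower and 8 higher, with a median log2 ratio of -0.07; SYNCRIP (-0.33), HNRNPUL2 (-0.25) and HNRNPR (-0.21) differed most.

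The genes furthest below control included SOAT1, which esterifies cholesterol for storage, SDHD, a subunit of succinate dehydrogenase, and the gel-forming mucins MUC5AC and MUC5B. SOAT1 (chromosome 1, 179293714 to 179358680) had 2000 counts in the control and 498 in the HNRNPF siRNA library, 3.97-fold lower (95% interval 3.61 to 4.41). SDHD, whose symbol another gene in the table shares, had 2676 and 928 counts, a log2 ratio of -1.52 (95% interval -1.63 to -1.41). MUC5AC had a log2 ratio of -1.39 (95% interval -1.57 to -1.22) and MUC5B of -1.45 (95% interval -1.70 to -1.22), although with 0.1 added to the authors' FPKM MUC5B was at -0.92 and FAM156A at -0.79, less than 2-fold lower; the authors' own log2 fold changes were -1.01 for MUC5B and -0.82 for FAM156A. Others among the 12 lowest were CDRT4 (-2.13), MAIP1 (-2.02), NAP1L5 (-1.42), HNRNPF itself, BICC1 (-1.33), SNX3 (-1.32), an endosomal sorting protein, and FAM156A (-1.28). Of the genes furthest above control the most abundant was PLK2, a polo-like kinase, which had 1027 counts in the control and 2074 in the HNRNPF siRNA library (log2 ratio 1.02, 95% interval 0.92 to 1.13). FST, which encodes the activin antagonist follistatin, was higher by 1.15 on the log2 scale (95% interval 0.92 to 1.39) and KRTAP2-3, a keratin-associated protein, by 1.41 (95% interval 1.16 to 1.69). The others among the 12 highest were ASDURF with 53 and 152 counts, PTH1R with 48 and 120, and, by log2 ratio, SRGAP3 (1.46), FMC1-LUC7L2 (1.26), ZNF616 (1.19), C1RL (1.18), NDUFA7 (1.16), SERINC2 (1.12) and RIMS2 (0.99). ASDURF, FMC1-LUC7L2, NDUFA7, C1RL, CDRT4 and FAM156A overlap other genes, share a symbol or have counts that are not whole, so the authors' counting may have split their reads and their ratios are uncertain.

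Of 12218 expressed genes, 108 were at least 2-fold higher and 72 at least 2-fold lower in the HNRNPF siRNA library. Without genes that share a symbol, readthrough genes and genes with counts that are not whole, 67 were higher and 37 lower. The counting interval excluded a ratio of 1 for each of the 108 and 72 genes, but the minimum level and the 2-fold rule nearly ensure this. It excluded a ratio of less than 2-fold for 20 of the higher and 28 of the lower ones. Most were of low abundance: among the 10654 genes that reached 5 CPM and 50 counts, 13 were at least 2-fold higher and 26 at least 2-fold lower. At 1.5-fold, 416 genes were higher and 328 lower. The median log2 ratio of all expressed genes was 0.00, and 90% of the genes lay between -0.44 and 0.49. Of the 32 genes that differed at least 4-fold, 30 stayed below 5 CPM and 25 were readthrough genes, shared a symbol or had counts that are not whole, against 19.9% of all expressed genes. In simulated libraries of these depths, 10 unchanged genes passed 2-fold from counting error alone, and 284 did when a biological dispersion of 0.04 was added, so the counts of genes depend on a spread that 1 library per group cannot show.

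**Figure D1:**
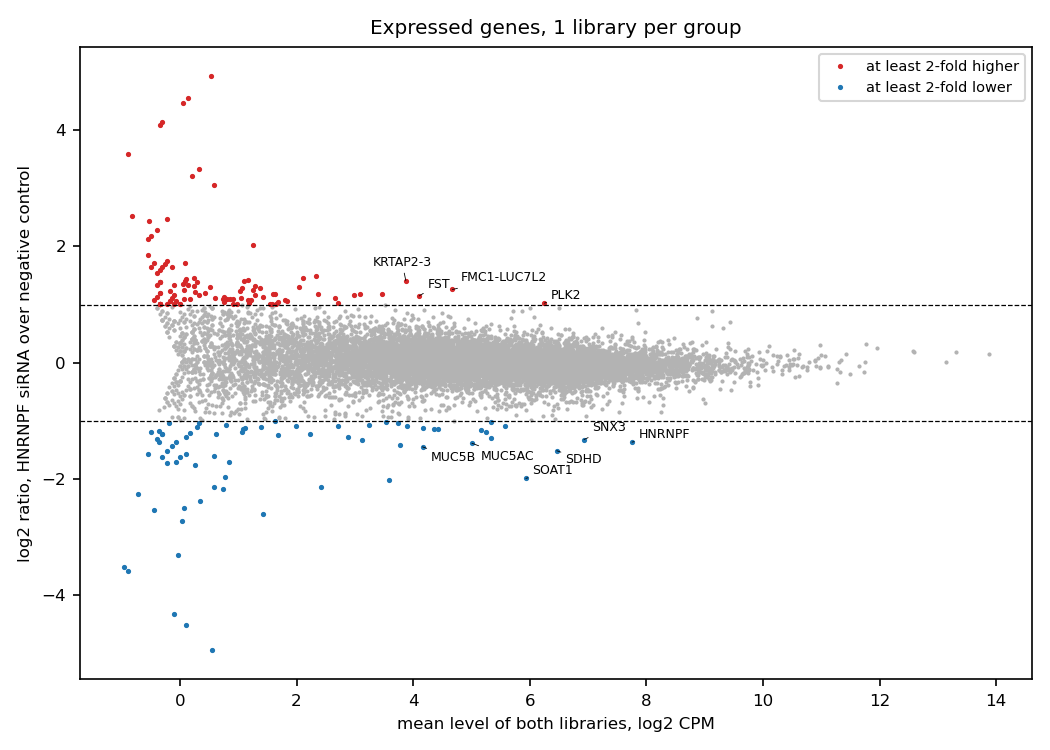
Log2 ratio of the HNRNPF siRNA library over the negative control against the mean level of both libraries (log2 CPM) for the 12218 expressed genes, each point 1 gene; dashed lines mark 2-fold, and 10 named genes that reached 20 CPM are labelled. The 108 higher (red) and 72 lower (blue) genes lie mostly at the low end, while HNRNPF, SOAT1, SDHD and SNX3 stand below the cloud at higher levels.

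Of 40 lists with at least 5 expressed members, 15 had a median outside the central 95% of random lists matched on size and expression. Of these, 9 lay below and 6 above. If genes varied independently, 2.0 would fall outside at the nominal rate of 5%, and somewhat more at the 6.70% of simulated unchanged lists. Genes of a list can vary together between cultures, so neither rate need hold for these lists. The genes of cholesterol biosynthesis were lower nearly throughout, with 22 of 23 expressed members below control, a median log2 ratio of -0.30 and a percentile of 0.0. HMGCS1 (-0.71), INSIG1 (-0.70), the sterol-regulated anchor of the pathway's transcription factor, and IDI1 (-0.66) differed most, and the counting interval lay below 0 for 16 members. Genes of fatty acid synthesis and desaturation were lower in 12 of 16 members (median -0.17, percentile 0.34), led by the desaturases SCD (-0.45) and FADS1 (-0.43) and by ACSL4 (-0.43), which activates polyunsaturated fatty acids. Without the 6 members that carry the heptamer GGAAGAA in the 3' untranslated region (UTR), described below, the fatty acid list had a median of -0.10 and a percentile of 9.13, inside the range of random lists. The cholesterol list without its 4 carriers kept a median of -0.28 and a percentile of 0.0.

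Mitotic genes were lower together, while G1/S genes were not set apart from random lists. Of 28 genes of the G2/M list, 25 were lower (median -0.20, percentile 0.01), among them the mitotic kinesin KIF20A (-0.48), DLGAP5 (-0.41) and the proliferation marker MKI67 (-0.38). The G1/S list had a median of -0.07 and a percentile of 17.4, with CCNE2 at -0.38, CDT1 at 0.30 and E2F1 at 0.22. The cell-cycle inhibitor CDKN1A was lower by more than 2-fold, with 576 counts in the control and 257 in the HNRNPF siRNA library (log2 ratio -1.15, 95% interval -1.37 to -0.94), and CCND1 was lower by a smaller margin (-0.30), while MYC was higher (0.30). CDKN1A, TP53INP1 (-0.89) and RRM2B (-0.63) led the p53 target list, of which 13 of 21 members were lower (median -0.15, percentile 0.42), and 8 were higher.

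Of the lists of inflammatory and stress responses, 3 were lower. The list of NF-kappaB targets, cytokines and chemokines had 13 of 16 expressed members below control, with a median of -0.30 and a percentile of 0.01. Among members at 5 CPM and 50 counts, the macrophage growth factor CSF1 (-0.74), the apoptosis inhibitor BIRC3 (-0.73) and the cytokine IL11 (-0.58) differed most. In the whole list 3 members were higher. The counting interval lay below 0 for 8 members and above 0 for 1. Targets of NRF2, the transcription factor of the oxidative stress response, were lower in 15 of 21 members (median -0.22, percentile 0.01). At 5 CPM and 50 counts, the aldo-keto reductases AKR1C1 (-0.94) and AKR1C3 (-0.51) and the glutathione synthesis subunit GCLM (-0.47) differed most. The counts of AKR1C1 and AKR1C3 are not whole, so their values are less certain. Without the 5 members that carry GGAAGAA, AKR1C1 and GCLM among them, the NRF2 list had a median of -0.14 and a percentile of 0.71. Of 18 genes of the unfolded protein response 15 were lower (median -0.13, percentile 1.77), among them the chaperones CALR (-0.70) and HSPA5 (-0.34), and HERPUD1 (-0.35).

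Targets of YAP and TEAD, the transcription factors at the end of the Hippo pathway, were higher: 19 of 20 members lay above control, with a median log2 ratio of 0.24, above all 10000 random lists. CCN1 had 10375 counts in the control and 15511 in the HNRNPF siRNA library (log2 ratio 0.59, 95% interval 0.56 to 0.63), ANKRD1 a log2 ratio of 0.58 and CCN2 of 0.53. The ecto-nucleotidase NT5E was the single member below control, at -0.33; it carries GGAAGAA in its 3' UTR and was named after its value was seen. Immediate early genes, which respond within minutes to growth factors and stress, had a median of 0.13 (percentile 98.96), with EGR1 at 0.68, IER2 at 0.55 and DUSP1 at 0.52 and with 13 of 21 members higher. With a minimum of 5 CPM and 100 counts this list had a percentile of 79.9, with the authors' FPKM 88.6, with the mean of the members 97.2 and with the trend of GC content and transcript length removed 91.0, all inside the range of random lists. The integrin list had 8 of 12 members lower (median -0.16, percentile 2.36). The lower members included ITGB3 (-0.89), whose symbol another gene shares, ITGB4 (-0.60) and ITGA3 (-0.34). The other 4 were higher, 2 of them at least 1.5-fold and the highest at 1.135, against 2 members at least 1.5-fold lower. By the mean of its members the integrin list lay at percentile 39.3 and with the trend removed at 3.36, so its place outside the range is not firm.

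Mitochondrially encoded transcripts and cytosolic ribosomal protein transcripts were higher. All 13 mitochondrially encoded genes were above control (median 0.25, above all 10000 random lists), with MT-ND4L at 0.70, MT-ND3 at 0.63 and MT-ND6 at 0.46, and together they took 4.80% of the control counts and 5.62% of the counts of the HNRNPF siRNA library. Of 56 ribosomal protein genes 49 were higher (median 0.15, above all 10000 random lists), including RPL38 (0.48), RPLP2 (0.37) and RPLP1 (0.36). Nuclear genes of oxidative phosphorylation had a median of 0.05 (percentile 97.8) with 20 of 31 members higher, NDUFA1 (0.44) among them, against SDHD at -1.52. SR and SR-like splicing factors and the kinases that phosphorylate them were lower in 17 of 19 members (median -0.14, percentile 1.72), with SRSF8 at -0.52, CLK1 at -0.42 and SRPK2 at -0.41. Counts of SRSF8 are not whole, and the authors' log2 fold change for it was -0.05, so its value is uncertain. Core spliceosome genes had a median of 0.05 (percentile 99.3), with SNRPG (0.49) and SNRPD2 (0.36) higher and SF3B6 (-0.38) lower. Across genes, the log2 ratio was related to transcript GC content (Spearman's rho 0.26) and length (rho -0.11); genes are not independent replicates. With that trend removed, the percentile was 86.4 for oxidative phosphorylation, 12.7 for SR factors and 80.2 for the core spliceosome, each inside the range of random lists, and the mitochondrial and ribosomal lists stayed above all random lists. The SR list was also inside that range with the authors' FPKM (percentile 12.6), oxidative phosphorylation by the mean of its members (89.9) and the core spliceosome without genes that carry GGAAGAA (95.6).

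**Figure D2:**
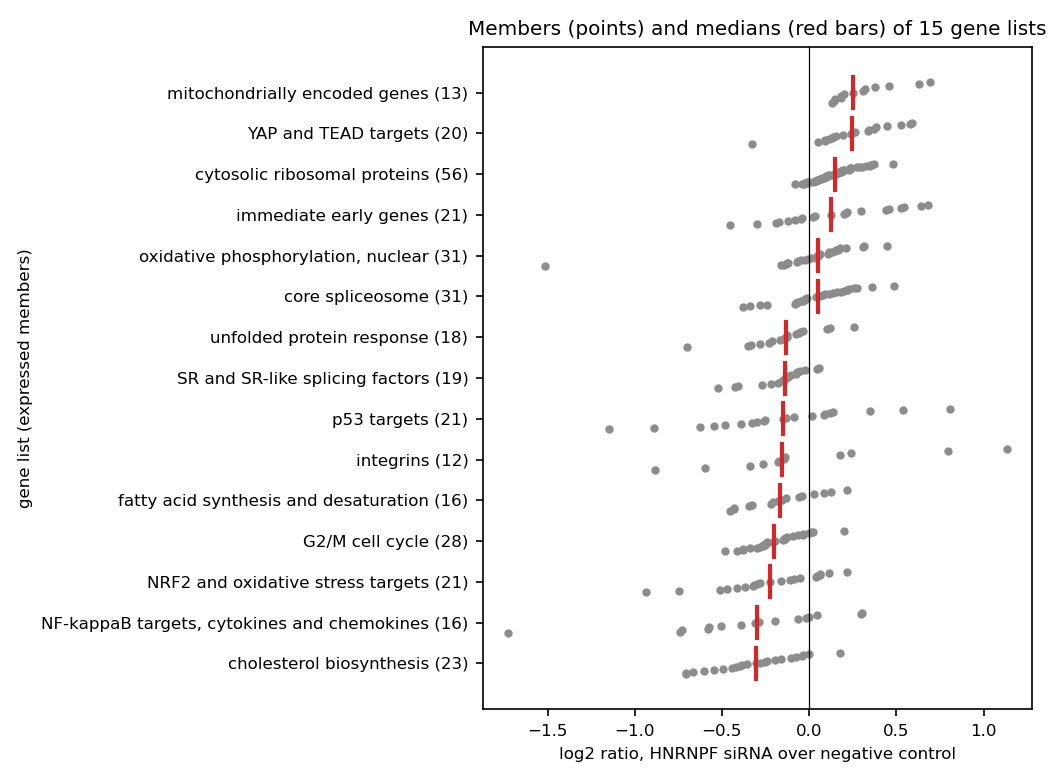
Log2 ratio of the HNRNPF siRNA library over the negative control for each expressed member (grey points) of the 15 lists outside the central 95% of matched random lists, with the median of each list as a red bar and the number of members in brackets. Medians run from -0.30 for cholesterol biosynthesis to 0.25 for mitochondrially encoded genes, and in most lists members lie on both sides of 0.

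The remaining 25 lists with 5 or more expressed members had medians inside the range of random lists. Interferon-stimulated genes had 13 members higher and 13 lower (median -0.01, percentile 25.7), with IFITM2 at 0.55, IFIT3 at -0.53 and USP18 at -0.52, and the list of RNA sensing and interferon induction had a median of 0.02 (percentile 65.5), with TLR3 at -0.53. Mesenchymal genes had a median of -0.08 (percentile 13.9), with ZEB2 at -0.41 and LOX at 0.31, and epithelial junction genes a median of 0.01 (percentile 45.0), with OCLN at -0.80 and ESRP2 at 0.87. Matrix proteases and the plasminogen system had a median of 0.01 (percentile 64.9), with ADAM8 at -0.62 and PLAUR at -0.52, extracellular matrix genes a median of 0.04 (percentile 93.5), and TGF-beta targets a median of -0.01 (percentile 48.9), with KLF10 at -0.50. Hypoxia targets lay near the edge (median -0.12, percentile 2.72), with BHLHE40 at -0.75. Targets of ATF4 had a median of 0.09 (percentile 93.7), with TRIB3 at 0.66 and ATF4 at 0.41. Apoptosis regulators (median -0.02, percentile 37.0) included APAF1 at -0.68 and BCL2L2 at -0.64. The Wnt and Notch list (median 0.02, percentile 51.8) held the Wnt antagonist DKK1 at 0.94 (95% interval 0.82 to 1.06). Percentiles of the others, which cover glycolysis, DNA repair, ferroptosis, lysosome and autophagy, heat shock, antigen presentation, growth factor receptors, breast cancer stem cell markers, histones, G1 regulators and nonsense-mediated decay among them, lay between 11.3 and 90.04. Ferroptosis genes lay outside the central 95% with the trend of GC content and length removed (percentile 1.02), mesenchymal genes with the authors' FPKM, and apoptosis regulators and the HNRNPF paralog list by the mean of the members.

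Few markers of other cell types were expressed. Of 18 haematopoietic markers 2 were, CD68 with 943 and 1078 counts (0.20) and CD8A with 61 and 55; of 10 endothelial markers 2, PECAM1 with 97 and 70 counts and KDR with 29 and 17; and of 11 fibroblast markers 2, COL1A1 (0.12, 95% interval -0.26 to 0.52) and PDGFRB (0.05, 95% interval -0.23 to 0.33). Of 10 markers of kidney or cervical lines 3 were expressed. Basal and keratinocyte markers included SFN (0.22) and S100A2, with 64 and 44 counts, and long nuclear RNAs were represented by TUG1 (0.09).

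A short sequence was more frequent in the 3' UTRs of the lower genes than in those of other genes. Among 10561 genes at 5 CPM and 50 counts with an annotated 3' UTR, 2159 carried the heptamer GGAAGAA there, and of 191 such genes at least 1.5-fold lower, HNRNPF left out, 122 did, or 63.9%, against 20.4% of all genes at that level. Among all expressed genes, low levels included, 158 of the 328 at least 1.5-fold lower and 22 of the 72 at least 2-fold lower carried it, so many of the lower genes did not. Among the 12 lowest genes, 7 carried it in the 3' UTR, among them SOAT1 and SDHD with 2 copies each and, with 1 each, MAIP1, NAP1L5, MUC5AC and BICC1; none of the 12 highest did, except that ASDURF has no annotated 3' UTR and was not searched. HMGCS1, INSIG1, SCD, FADS1, ACSL4, CSF1, BIRC3, AKR1C1, GCLM, CALR, RRM2B, MKI67, CCND1, SRSF8, SRPK2, OCLN, BHLHE40, APAF1, BCL2L2, CCNE2 and the paralog GRSF1 carried it as well. KIF20A, IDI1 and TP53INP1 carried the shorter match GAAGAAA, CDKN1A carried GAAGAA alone and IL11 carried none. Higher genes held such matches too: SRGAP3, FST and LOX carried GAAGAAA, and PLK2 and CCN2 carried GAAGAA alone. The mean log2 ratio was -0.15 for 983 genes with GGAAGAAA (SE across genes 0.01). It was -0.06 for 1176 genes with GGAAGAA without a following A (SE 0.008). For 1392 genes with GAAGAAA but not GGAAGAA it was -0.03 (SE 0.006). It was 0.02 for 1076 genes with GAAGAA alone (SE 0.007) and 0.03 for 5934 genes with none (SE 0.003). HNRNPF itself carries the heptamer in its coding sequence and not in its 3' UTR, in exon 3 of 3 of the transcript HNRNPF-204, at GRCh38 chromosome 10, 43387507 to 43387513.

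**Figure D3:**
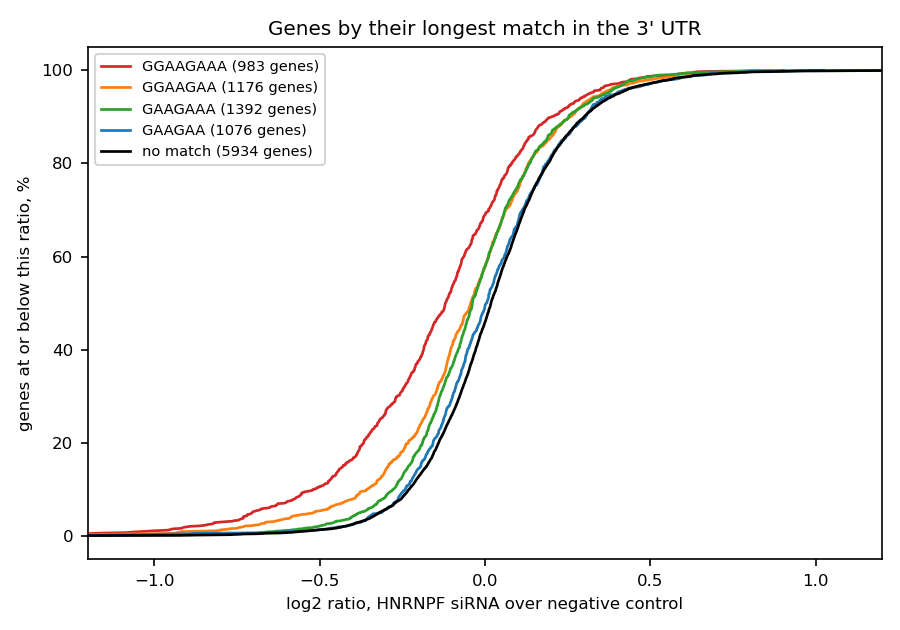
Cumulative share of genes (%) against their log2 ratio of the HNRNPF siRNA library over the negative control, for genes grouped by the longest match in their 3' UTR. The curve of the 983 genes with GGAAGAAA lies furthest towards lower ratios and that of the 1076 genes with GAAGAA alone runs close to that of the 5934 genes with no match.

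The authors' deposited table lists 4303 genes with a false discovery rate under 0.05 in their own test of these 2 libraries, 2289 higher and 2014 lower. By the authors' fold changes 153 of them were at least 2-fold higher and 100 at least 2-fold lower, and HNRNPF had a log2 fold change of -1.32. Such a test on the reads of 2 libraries compares those libraries, not the conditions. Of the 253 genes past both thresholds in the authors' deposited table, 146 were at least 2-fold in the same direction here and 66 were below the expression minimum used here.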

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

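The settings that removed the GC and length trend, the genes with GGAAGAA, the genes that share reads and the genes not annotated as protein-coding were chosen after the data were seen. The HNRNPF log2 ratio ran from -1.38 to -1.32 over the other scalings, inside its counting interval. The counts of genes at least 2-fold higher (108) and lower (72) depended on the minimum level and on the fold. With a minimum of 1 count they were 619 and 289, with 5 CPM and 100 counts 13 and 26, at 1.5-fold 416 and 328, and at 4-fold 16 and 16. With 5 CPM and 100 counts fewer genes were higher than lower; the cause was not tested. Without genes that share a symbol, readthrough genes and genes with counts that are not whole, 67 were higher and 37 lower. Under the scalings, prior counts, the trend removal, the removal of heptamer carriers, protein-coding genes alone and the authors' own fold changes both counts stayed within 1.5 times, from 81 to 153 higher and from 50 to 100 lower. The number of lists outside the range of random lists was 15 under each scaling by counts. A scaling adds nearly the same constant to every log2 ratio, so the percentiles could hardly move and this is no check. The number was 14 with the authors' FPKM, with 5 CPM and 100 counts and with the mean. It was 13 without genes that carry GGAAGAA and 11 with the trend removed. In that order, 13, 14, 12, 13 and 10 of these were among the 15. Of the list medians under all alternatives, 348 stayed within the main median's bootstrap interval and 12 moved outside it. That interval came from redrawing each list's members at random 2000 times. Of the values of the 24 genes at the extremes, 165 stayed within their counting interval and 2 did not. These 2 were MUC5B at -0.92 and FAM156A at -0.79 with 0.1 added to the authors' FPKM, and the cause was not tested. No list median or gene value changed sign where it had been called. The alternatives planned for several libraries per group were not run because each group has 1. At this depth 10 unchanged genes among 20323 simulated ones passed 2-fold from counting error alone.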

Other observations

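Over the 312 pathways annotated in the authors' table with 10 to 300 expressed members, a search beyond the fixed lists, the lowest median log2 ratio was that of steroid biosynthesis (18 genes, -0.21, percentile 0.09), with 15 members lower. The JAK-STAT signaling pathway had 61 of 95 members lower (median -0.09, percentile 0.12), and kept a median of -0.09 in the 75 members without GGAAGAA in the 3' UTR. At the other end, fat digestion and absorption had the highest median (16 genes, 0.16, percentile 98.9), with 14 members higher. Its percentile was 96.9 without heptamer carriers and 94.6 with the GC and length trend removed, both inside the central 95%. Oxidative phosphorylation (125 genes, median 0.13), the ribosome (132 genes, median 0.12) and RNA polymerase (35 genes, median 0.11, percentile 99.8) were higher. So was the multi-species Hippo signaling set (25 genes, median 0.11, percentile 98.9), whose 20 members without the heptamer had a median of 0.18. The full Hippo signaling pathway showed no such shift, with 58 of 119 members higher and 61 lower (median 0.00, percentile 57.3). Pathways overlap and their genes can vary together, so more than about 1 in 20 may lie outside the central 95% by chance.

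Among the tests of explanations that follow, those of the control siRNA's sites and of counting error in unchanged genes were chosen after the result was seen; the others were written before theirs were computed, although the patterns came from the same data. Among genes at 5 CPM and 50 counts, 122 of the 191 at least 1.5-fold lower carried a single heptamer in the 3' UTR; of all 328 expressed genes at least 1.5-fold lower, 158 did. Of 16044 heptamers scored without regard to HNRNPF, GGAAGAA had the lowest score (-15.7), followed by the overlapping GAAGAAA (-11.2), while the median size of a score was 0.72. When an HNRNPF heptamer was picked on alternate genes, GGAAGAA was picked both times and marked 71 of 106 and 51 of 85 lower genes left out of the choice, at least 3.21 times its share of the other genes. The heptamer begins at base 859 of HNRNPF-204, 11 bases after 848, the number in the library's name, and the extra step down with a following A is the pattern of pairing with bases 2 to 8 of a guide strand, so off-target silencing by the HNRNPF siRNA is a candidate explanation for the lower genes that carry it, SOAT1 and SDHD included. The offset holds in 1 of 5 annotated HNRNPF transcripts and the siRNA sequences were not among the sources used here. Neither the GC and length trend nor counting error accounts for the lower genes, since 87.7% of the 328 genes stayed 1.5-fold lower without the trend, and at most 86 genes were 1.5-fold lower in any of 200 random divisions of each gene's counts between the libraries. Lower HNRNPF itself, indirect effects of off-target silencing and the spread between cultures, which 1 library per group does not show, stay open. This holds above all for lower genes without the heptamer in the searched 3' UTR, such as CDKN1A and SNX3, which carry GAAGAA alone. Their coding sequences and the 3' UTRs of their other transcripts were not searched. A second siRNA or a rescue would be needed to separate these explanations.

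The genes at least 1.5-fold higher were not explained by the tests made. After removal of the GC and length trend 83.5% of the 416 genes stayed 1.5-fold higher, and at most 78 genes were 1.5-fold higher in any of the random divisions of the counts. If the control siRNA silenced genes through its own seed, carriers of its match would be higher in the HNRNPF siRNA library. The highest-scoring heptamers, CGGAGAA and TCGGAGA, overlap. CGGAGAT, TGGAGAA and ACGGAGA, also among the highest, share GGAGA with them, but all were ranked on the same genes. The held-out choice was not the same heptamer in both sets, although both picks hold GGAGA. TCGGAGA, picked on the first set of alternate genes, marked 5 of 71 higher genes left out of the choice. This was 3.86 times its share of the other genes. TGGAGAA, picked on the other set, was at 0.93 times its share of the other genes. Sites of the control siRNA, an effect of lower HNRNPF and the spread between cultures therefore cannot be told apart for these genes. Indirect effects of off-target silencing by the HNRNPF siRNA were not tested and stay open for them as well. Of the 1.5-fold higher genes at 5 CPM and 50 counts, 11 carried CGGAGAA, 12 carried TCGGAGA and 129 carried neither of these. They made up 4.62% of 238 genes with CGGAGAA, 5.97% of 201 with TCGGAGA and 1.27% of 10183 with neither. Of 56 genes with TCGGAGAA, which holds both, 7 (12.5%) were 1.5-fold higher. Their mean log2 ratio was 0.19, against -0.01 for genes with neither. The sequences were picked on these same genes, so these shares are no test of them.

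The cholesterol biosynthesis genes had a median below all 10000 random lists, and SOAT1, which stores free cholesterol as ester, was 3.97-fold lower. The GC and length trend does not account for the list, whose median stayed at -0.33 and percentile 0.0 after its removal. Direct silencing through GGAAGAA does not account for the list as a whole either. The heptamer was carried by 4 of 23 members, HMGCS1 and INSIG1 among them, which is 0.87 times its share of the other genes. The 19 without it had a median of -0.28. These include IDI1, which carries GAAGAAA, so silencing of single members stays open. Over all genes the mean log2 ratio was -0.03 with GAAGAAA and 0.03 with no match. One hypothesis is that less esterification leaves more free sterol, which would lower these genes and raise targets of the sterol receptor LXR. The median of 6 LXR targets was 0.03, with members that go both ways. ABCA1 was at 0.55 (95% interval 0.35 to 0.74) and SREBF1 at -0.13 (95% interval -0.26 to -0.003). For ABCG1 (0.33), NR1H3 (0.14), LPCAT3 (-0.08) and MYLIP (-0.14) the interval spanned 0, so counting error alone leaves their direction open. The free-sterol route, an effect of lower HNRNPF on sterol genes and the spread between cultures therefore cannot be told apart. Other indirect effects of off-target silencing were not tested. Sterol levels were not analysed here.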
